A study of Homo sapiens with 14 samples.

How the data were processed

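The 14 samples are of PANC-1, an established human pancreatic ductal carcinoma cell line, kept in a medium low in nutrients and sampled at 6 times up to 48 h. There were 4 samples at 0 h and 2 each at 3, 6, 12, 24 and 48 h, and the group and replicate number of each were taken from the sample titles. Per the labels' protocols, total RNA was column-purified, copied and labelled with Cy3 by an oligo(dT)-primed one-colour kit for low RNA input, and hybridised to a whole-genome Agilent array. A one-colour array gives 1 brightness per spot, and levels are compared between arrays, not between probes.

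The deposited values are intensity values on a linear scale from the scanner software Agilent Feature Extraction 9.5.3.1, per the file headers. Per the file headers, the software subtracted a spatially fitted background surface, evened out the signal across the array and replaced the dimmest spots by a positive surrogate. Surrogates made up 23.6% to 31.9% of the spots of an array. The values were not scaled between arrays. A spot counted as well above background where the software said so, a call that per the file headers rests on 13 times the background noise. Such surrogates and the subtraction limit what can be read from dim probes, whose fold changes depend on the background method. The gene list that the study made with another program is not analysed here.

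Each array held 45015 spots, of which 43376 were not controls and stood for 41000 probes. No used spot was saturated, and between 76 and 165 outlier spots per array were left out. The 75th percentile of the intensity lay between 611 and 1109, and 54.8% to 62.6% of the spots were well above background. For arrays, the number of arrays limits the precision. Signals were taken to log2, each array's 75th percentile was subtracted, and spots of one probe were averaged. Probes were named through current RefSeq gene tables, 23958 of them by a RefSeq accession, 363 by another accession, 2482 by a current symbol and 984 by an older symbol. That gave 27787 probes a gene and left 13213 without one, which were not used. Of 17849 genes, 7251 had more than 1 probe, and the probe with the highest mean signal over all arrays stood for the gene. Among 3993 genes with at least 2 probes well above background on all 10 arrays of the main comparison, 133 had probes that moved beyond 0.5 log2 units in both directions. Probe positions are those of the array files, on the human build hg18, and no exon or untranslated region was assigned because annotation of that build was not used here.

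Comparisons and tests were chosen before the data were examined. Genes entered a test where the probe was well above background on every array of at least 1 time group in the fit. Late arrays, the 6 of 12, 24 and 48 h, were compared with the 4 of 0 h in a fit of those 10 arrays, as the series design states it. Each time point against 0 h, and neighbouring time points, were contrasts of a means model over all 14 arrays, except that 24 h against 12 h, which lie on different slides, had the slide as a term. All were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the package data.table (version 1.17.8), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Prepared tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. In all, 27 gene lists were written down beforehand and tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the arrays. The lists overlap by 1 gene in each of 6 pairs. Errors given as ± are standard errors of the fit unless SD is stated.

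Genes were named by a rule: for the late comparison the 8 that rose most and the 8 that fell most among genes past the threshold, measured on every array of at least 1 side and with all 6 late arrays on one side of all 4 arrays of 0 h, and up to 4 members of each list with the largest change past the threshold. For other comparisons the rule took 3 genes each way. It gave 146 genes, and 1 further gene it picked is not named. Of these, 3 are not reported here and were not left out for their values. Genes that the rule did not pick appear only in the closing section and were chosen after their values were seen.

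Arrays lay on 4 slides. Slides 1 and 2 each held 1 array of 0, 3, 6 and 12 h, and slides 3 and 4 each held 1 array of 0, 24 and 48 h, so every change against 0 h was also computed within slides and with the slide as a block. The position on the slide was tied to the time point. Whether samples with the same replicate number deviate together was checked over 15 pairs, and 3 had a correlation over 0.1, so the numbers were not used for pairing. All 3 shared slides. Of all pairs, 5 of 9 on the same slides and 0 of 12 on different slides had a correlation over 0.1. Deviations thus followed the slide in part, which the main models leave out except for 24 h against 12 h.

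Scripts were tested on simulated arrays with 200 genes changed by a known amount. For the late comparison, with 12583 genes, 35.8% of the 1.5-fold, 76.1% of the 2-fold and 93.9% of the 4-fold changes were recovered, with 10 false calls. For 3 h against 0 h, with 12629 genes, the shares were 50.7%, 77.6% and 95.5%, with 8 false calls. For 24 h against 12 h, with 12629 genes, they were 19.4%, 56.7% and 81.8%, with 6 false calls. A shifted gene list was found in each of the 3 simulations and 0 of the 26 other lists passed. The simulated noise was independent between genes, so this does not test list calls where members vary together. In the late comparison the estimated correlation within a list reached 0.793. The simulations also changed far fewer genes than passed in the data.

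Alternatives tried were normexp background correction of the raw signals with an offset of 50, quantile normalization, median centring, no filter or a filter on all arrays, the mean of all probes of a gene, an intensity trend in the prior variance, a minimum change of 2-fold, blocks for slide and replicate number, each slide pair alone, all 14 arrays in the late fit, and leaving out each array in turn. After the data were seen, scaling to 5 spike-in probes, leaving out the 48 h arrays, and leaving out the 3 h and 6 h arrays of slide 1 were added. In the closing section, 100 of the 210 possible splits of the 10 arrays were drawn, 40 gene families defined by symbol were tested, and each ribosomal protein gene was set against all other genes, at least 20, within 0.25 log2 units of its signal. The symbol patterns of 8 families were narrowed once after their results were seen, to leave out kinases, receptors, assembly factors and pseudogenes, and with the wider patterns keratins and complex I had passed.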

Results

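PANC-1 cells, a human pancreatic ductal carcinoma line, were profiled on Agilent arrays before and during culture in nutrient-deprived medium of unstated composition. There were 4 arrays at 0 h, 2 at each later time and no timed controls in other medium. Deprivation, medium change and time in culture thus cannot be told apart. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. In the late comparison, whose model treats 12, 24 and 48 h as one group, that spread also includes differences between these times. The correlations between genes estimated there include them too. Changes are differences of log2 intensity scaled to each array's 75th percentile, and gene positions are those of the probes on the human build hg18. Where a probe was not well above background on any array of one side, the change is a bound, "at least N-fold". That bound sets the bright side's mean against the dim side's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. It holds only under the background subtraction of the main analysis. With normexp some changes were smaller than their bound or turned, such as PAQR9 at 6 h, at -0.14, and HSPA2 at 6 h, at 0.28. Median changes of all genes lay between -0.05 and 0.09 log2 units against 0 h. Scaled to 5 spike-in probes instead, an alternative added after seeing the data, the median of all genes moved to -0.357 in the late comparison, -0.273 at 24 h and -0.822 at 48 h, so changes at late times are relative to the array's other genes.

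The main comparison set the late arrays of 12, 24 and 48 h against 0 h. The 8 genes with the largest rises included the stress factor CREBRF and the ubiquitin ligase NEURL3. CREBRF, a regulator of the CREB3 family of stress factors (chromosome 5, 172496411 to 172496470), rose by 5.17 ± 0.0849, or 35.9-fold (limma adjusted p = 2.11e-10, 6 against 4 arrays). NEURL3 (chromosome 2, 96527146 to 96527205) rose by 5.58 ± 0.252 (adjusted p = 6.82e-08), and the chemokine CCL5 (chromosome 17, 31223445 to 31223504) by 4.90 ± 0.155 (adjusted p = 9.84e-09). The trypsin inhibitor SPINK1 (chromosome 5, 147184404 to 147187778) was at least 20.4-fold higher, the leukocyte adhesion molecule SELE (chromosome 1, 167958673 to 167958732) at least 14.9-fold and the metalloproteinase MMP10 (chromosome 11, 102146615 to 102146674) at least 9.58-fold, with adjusted p of 3.43e-06, 3.7e-05 and 3.54e-07. SLC22A15, a membrane transporter (chromosome 1, 116413334 to 116413393), was at least 15.8-fold higher (adjusted p = 1.38e-07), and ATP6V0D2, a subunit of the vacuolar proton pump (chromosome 8, 87234421 to 87234480), at least 8.68-fold (adjusted p = 2.89e-06).

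The 8 genes with the largest falls included CDC25A and E2F2. CDC25A, the phosphatase that activates cyclin-dependent kinases (chromosome 3, 48174128 to 48174187), fell by 4.45 ± 0.602 (adjusted p = 0.000102) and was well above background on 3 of the 6 late arrays. The arginine methyltransferase PRMT6 (chromosome 1, 107402945 to 107403004) fell by 4.05 ± 0.267 (adjusted p = 7.22e-07). E2F2, a transcription factor of the G1/S transition (chromosome 1, 23705520 to 23705579), fell by 3.90 ± 0.647 (adjusted p = 0.000412), while another of its probes gave +0.29. HAS3, a hyaluronan synthase (chromosome 16, 67708870 to 67708929), was at least 16.8-fold lower, RIBC2 (chromosome 22, 44206897 to 44206956) at least 7.74-fold, and FAM111B (chromosome 11, 58648678 to 58648737) at least 4.82-fold, with adjusted p of 1.69e-06, 4.68e-07 and 7.33e-09. PAQR9 (chromosome 3, 144162896 to 144162955) was at least 3.90-fold lower (adjusted p = 1.02e-08) and IFT70B (chromosome 2, 178123818 to 178123877), which has a close paralog, at least 5.76-fold (adjusted p = 1.79e-06). For each of these 16 genes all 6 late arrays lay beyond all 4 arrays of 0 h, and all genes named for this comparison changed the same way within each of the 4 slides.

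In all, 7965 of 12616 genes passed the test, 4022 higher and 3943 lower. With the slide as a block 7394 passed, 3698 higher and 3696 lower. On slides 1 and 2 alone, whose late arrays are all of 12 h, 8098 passed. On slides 3 and 4 alone, whose late arrays are of 24 and 48 h, 7289 passed. These counts therefore differ in time as well as in slide. The same holds for the range of within-slide medians given for a list in this late comparison. Scaled to the spike-in probes, 1597 were higher and 4760 lower. Of the 27 lists, 11 passed at the preset correlation and 0 of 27 by camera with an estimated one, where 6 passed unadjusted. The slide block moved the median of each list by at most 0.171. Unless stated, counts of list members were the same when adjusted over the list alone.

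**Figure D1:**
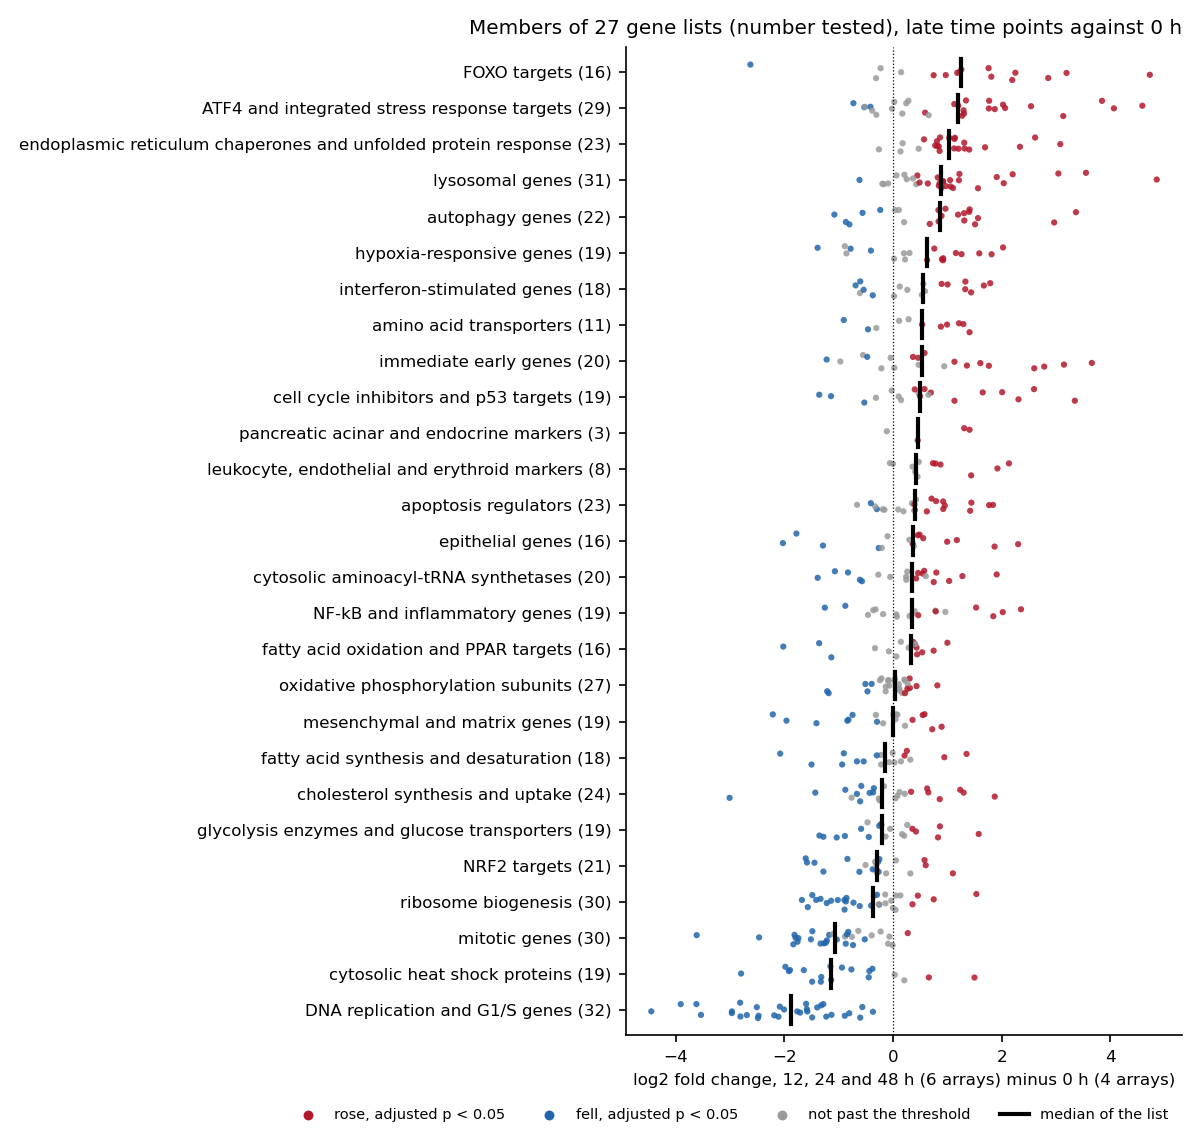
Log2 change of each measured member of the 27 gene lists between the 6 late arrays and the 4 arrays of 0 h (x axis, log2 units), 1 line per list, with the list medians marked. DNA replication genes lie below 0 throughout, with a median of -1.88, and the median of the integrated stress response list is 1.20.

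Targets of ATF4, the transcription factor of the integrated stress response, were higher at late times. Of 29 measured, 17 rose, 3 fell and 9 did not pass, or 17 and 4 adjusted over the list alone, with a median of 1.20, or 0.80 with spike-in scaling, and within-slide medians of 0.868 to 1.41 (camera adjusted p = 0.000374). The call did not hold with an estimated correlation (adjusted p = 0.244 with an estimated correlation). ATF3, a stress-induced repressor, rose by 4.59 ± 0.148, DDIT3 (CHOP), a driver of stress-induced death, by 4.07 ± 0.31, and the chromatin protein NUPR1 by 3.85 ± 0.174. PPP1R15A, which recruits the phosphatase for eIF2-alpha, rose by 3.13 ± 0.111. Chaperones and regulators of the endoplasmic reticulum also rose: 19 of 23 members rose, none fell and 4 did not pass, with a median of 1.04, or 0.63 with spike-in scaling, and within-slide medians of 0.458 to 1.34 (camera adjusted p = 0.000168, adjusted p = 0.519 with an estimated correlation). HSPA5 (BiP), the main chaperone of this compartment, rose by 3.08 ± 0.168, its cochaperone DNAJB9 by 2.62 ± 0.131, the stress sensor ERN1 by 2.34 ± 0.486 and the chaperone HYOU1 by 1.70 ± 0.208.

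Genes of DNA replication and the G1/S transition fell, each by the probe that stood for it: all 32 measured members passed, with a median of -1.88 and within-slide medians of -2.27 to -1.22 (camera adjusted p = 1.28e-08, adjusted p = 0.437 with an estimated correlation). For the member E2F2, another probe, well above background on all 10 arrays, gave +0.29. GINS4, part of the replicative helicase and well above background on 2 of 6 late arrays, fell by 3.62 ± 0.449 and POLE2, a subunit of polymerase epsilon, by 3.53 ± 0.497. Of 30 mitotic genes, 20 fell, 1 rose and 9 did not pass, with a median of -1.07 and within-slide medians of -1.42 to -0.287 (camera adjusted p = 0.000437, adjusted p = 0.519 with an estimated correlation). The proliferation marker MKI67 fell by 3.61 ± 0.68 and was well above background on 3 of 6 late arrays, the mitotic kinesin KIF20A fell by 2.46 ± 0.354, the kinase PLK1 by 1.83 ± 0.162 and the checkpoint kinase BUB1B by 1.81 ± 0.347. Of 19 cell cycle inhibitors and p53 targets, 10 rose, 3 fell and 6 did not pass, with a median of 0.50 (camera adjusted p = 0.0475, adjusted p = 0.173 with an estimated correlation), but with spike-in scaling 6 rose and 4 fell, with a median of 0.09. The list call was lost with the slide as a block (adjusted p = 0.0524, median 0.54, and 0.0139 to 0.122 over the alternatives tried). The inhibitor CDKN1C (p57) rose by 3.35 ± 0.309, the antiproliferative BTG1 by 2.60 ± 0.18 and the growth-arrest genes GADD45A and GADD45B by 2.31 ± 0.0875 and 2.01 ± 0.188.

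Targets of FOXO transcription factors, which are active when insulin and growth factor signalling is low, rose in 12 of 16 cases, with 1 fall and 3 not past. Their median was 1.25 and the within-slide medians 1.09 to 1.52 (camera adjusted p = 0.000763, adjusted p = 0.0509 with an estimated correlation). The ubiquitin ligase adaptor KLHL24 rose by 4.73 ± 0.103, the PI3K inhibitor PIK3IP1, well above background on 2 of 4 arrays of 0 h, by 3.19 ± 0.13 and the cyclin CCNG2 by 2.86 ± 0.189. TXNIP, a thioredoxin inhibitor that curbs glucose uptake, was the member that fell, by 2.62 ± 0.277. Of 22 autophagy genes, 14 rose, 5 fell and 3 did not pass, with a median of 0.87, or 0.84 with bounds in place of fitted values and 0.46 with spike-in scaling (camera adjusted p = 0.00608, adjusted p = 0.173 with an estimated correlation). Within slides the median lay between 0.562 and 0.993. MAP1LC3B (LC3B), a coat protein of the autophagosome, rose by 3.37 ± 0.0897, its relative GABARAPL1 by 2.97 ± 0.199, and TP53INP2 and WIPI1, both of autophagosome formation, by 1.57 ± 0.138 and 1.51 ± 0.184. Of 31 lysosomal genes, 22 rose, 1 fell and 8 did not pass, with a median of 0.89, or 0.49 with spike-in scaling, and within-slide medians of 0.409 to 1.08 (camera adjusted p = 0.000168, adjusted p = 0.496 with an estimated correlation). The protease cathepsin S (CTSS) rose by 3.55 ± 0.185, the sialidase NEU1 by 3.04 ± 0.24 and the cholesterol carrier NPC2 by 2.20 ± 0.27.

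Cytosolic heat shock proteins fell in 15 of 19 cases, with 2 rises and 2 not past. The median was -1.13 and the within-slide medians -1.16 to -0.977 (camera adjusted p = 0.000766, adjusted p = 0.0509 with an estimated correlation). HSP90AA1, an inducible HSP90, fell by 1.91 ± 0.203 and the cochaperone DNAJA1 by 1.89 ± 0.119. HSPA1L was at least 3.65-fold lower. HSPA1A, an inducible HSP70 with near-identical copies, fell by 1.98 ± 0.627 (adjusted p = 0.0184), a call lost on slides 3 and 4 alone (adjusted p = 0.191, from a range of 1.44e-09 to 0.191). The late arrays of those slides are of 24 and 48 h only, so that loss cannot be assigned to the slides rather than to the times. Of 30 ribosome biogenesis genes, 18 fell, 4 rose and 8 did not pass, with a median of -0.37, or -0.78 with spike-in scaling, and within-slide medians of -0.484 to -0.29 (camera adjusted p = 0.00608, adjusted p = 0.0698 with an estimated correlation). The assembly factors RRS1, TSR1 and MRTO4 fell by 1.67 ± 0.104, 1.57 ± 0.125 and 1.48 ± 0.135, while MYC, the transcription factor that drives this programme, rose by 1.54 ± 0.0836. Of 21 targets of the antioxidant factor NRF2, 11 fell, 3 rose and 7 did not pass, with a median of -0.30, or -0.70 with spike-in scaling (camera adjusted p = 0.0475, adjusted p = 0.347 with an estimated correlation). That call was lost with the slide as a block (adjusted p = 0.0524) and under quantile normalization (adjusted p = 0.0527, and 0.00364 to 0.139 over the alternatives tried). The peroxiredoxin PRDX1 fell by 1.60 ± 0.0948, the glutathione synthesis subunit GCLM by 1.44 ± 0.0984 and heme oxygenase HMOX1 by 1.28 ± 0.0922.

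Metabolic lists moved in both directions and their set tests did not pass. Of 19 genes of glycolysis and glucose uptake, 4 rose, 8 fell and 7 did not pass (median -0.21, or -0.61 with spike-in scaling and -0.32 under quantile normalization, camera adjusted p = 0.407). Hexokinase HK2 rose by 1.58 ± 0.134, while triose phosphate isomerase TPI1 and lactate dehydrogenase LDHA fell by 1.28 ± 0.137 and 1.03 ± 0.203. Of 24 cholesterol genes, 7 rose, 9 fell and 8 did not pass (median -0.20, or -0.61 with spike-in scaling, camera adjusted p = 0.556). SREBF2, a transcription factor that activates genes of this pathway, rose by 1.87 ± 0.143. Of 18 genes of fatty acid synthesis, 4 rose, 7 fell and 7 did not pass (median -0.14, or -0.55 with spike-in scaling and -0.04 with normexp, camera adjusted p = 0.377). The elongase ELOVL6 and the lipase PNPLA3 fell by 2.07 ± 0.124 and 1.50 ± 0.23, and the phosphatase LPIN1 rose by 1.35 ± 0.101. Of 16 fatty acid oxidation and PPAR target genes, 7 rose, 3 fell and 6 did not pass. Their median was 0.33, their mean -0.003 and the camera direction up (adjusted p = 0.377), and the median was -0.07 with spike-in scaling and 0.20 under quantile normalization. With spike-in scaling 0 of them rose and 3 fell. ANGPTL4, a lipase inhibitor, fell by 2.02 ± 0.208 and the carnitine carrier SLC25A20 by 1.13 ± 0.0903. Of 27 subunits of oxidative phosphorylation, 6 rose, 5 fell and 16 did not pass, against 1 and 4 adjusted over the list alone. Their median of 0.04 had the opposite sign to the mean of -0.04 and to the camera direction (adjusted p = 0.786), and it was -0.02 under quantile normalization and -0.37 with spike-in scaling. The complex I subunits NDUFB3 and NDUFS3 fell by 1.21 ± 0.0723 and 1.18 ± 0.114, and NDUFB5 rose by 0.82 ± 0.166.

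Of 20 cytosolic aminoacyl-tRNA synthetases, 9 rose, 5 fell and 6 did not pass (camera adjusted p = 0.19), with a median of 0.35 that became -0.06 with spike-in scaling. AARS1 and SARS1 rose by 1.91 ± 0.0888 and 1.28 ± 0.0687, and FARSA and HARS1 fell by 1.38 ± 0.115 and 1.07 ± 0.106. Of 11 amino acid transporters, 6 rose, 2 fell and 3 did not pass (median 0.54, or 0.13 with spike-in scaling, camera adjusted p = 0.159). SLC3A2, the shared heavy chain, rose by 1.41 ± 0.189 and SLC43A1 and SLC38A1 by 1.30 ± 0.228 and 1.22 ± 0.0846. Of 19 hypoxia-responsive genes, 10 rose, 3 fell and 6 did not pass, or 11 and 4 adjusted over the list alone (median 0.63, or 0.22 with spike-in scaling, camera adjusted p = 0.0901). The angiogenic factor VEGFA rose by 2.03 ± 0.278, the MYC antagonist MXI1 by 1.82 ± 0.291 and the lysyl oxidase LOX by 1.59 ± 0.2, and the adenylate kinase AK4 fell by 1.39 ± 0.161.

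Inflammatory and signalling lists did not pass in the combined late comparison, but without the 48 h arrays 15 of the 27 lists passed, 10 of them shared with the 11. The 5 added were the inflammatory, interferon-stimulated, immediate early, apoptosis and amino acid transporter lists, with medians of 0.75, 0.83, 0.79, 0.27 and 0.79 (adjusted p = 0.0139, 0.0348, 0.0139, 0.0162 and 0.0348, the lowest among the alternatives, up to 0.677, 0.57, 0.519, 0.173 and 0.404 with an estimated correlation). Of 19 NF-kB and inflammatory genes, 6 rose, 2 fell and 11 did not pass (camera adjusted p = 0.219), with a median of 0.35 that became -0.06 with spike-in scaling. CXCL8, a neutrophil chemokine, rose by 2.02 ± 0.277, RELB by 1.85 ± 0.105 and the feedback inhibitor TNFAIP3 by 1.53 ± 0.203. Of 18 interferon-stimulated genes, 7 rose, 4 fell and 7 did not pass (median 0.55, or 0.14 with spike-in scaling, camera adjusted p = 0.256). The RNA sensor IFIH1 rose by 1.79 ± 0.306, IRF7 by 1.67 ± 0.0785 and MX1 by 1.33 ± 0.158. Of 20 immediate early genes, 11 rose, 2 fell and 7 did not pass, or 11 and 3 adjusted over the list alone (median 0.53, or 0.12 with spike-in scaling, camera adjusted p = 0.0767). The nuclear receptor NR4A1 rose by 3.15 ± 0.629, FOS, well above background on 2 of 4 arrays of 0 h, by 2.79 ± 0.322 and EGR1 by 2.60 ± 0.37, and EGR2 was at least 3.34-fold higher. Of 23 apoptosis regulators, 12 rose, 2 fell and 9 did not pass, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.0524), with a median of 0.40 that became -0.002 with spike-in scaling. BMF, a pro-death BCL2 relative, rose by 1.84 ± 0.253, the death receptor TNFRSF10B by 1.77 ± 0.183, CASP9 by 1.44 ± 0.0974 and the caspase inhibitor XIAP by 1.42 ± 0.0937.

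Markers of lineage were mixed. Of 19 mesenchymal and matrix genes, 5 rose, 7 fell and 7 did not pass (camera adjusted p = 0.386), with a median of 0.01 against a mean of -0.27 and a camera direction down. That median was -0.03 with the slide as a block, -0.13 under quantile normalization, -0.01 under median centring and -0.40 with spike-in scaling. SPARC, COL1A1 and THBS1, all matrix proteins, fell by 2.21 ± 0.236, 1.96 ± 0.204 and 1.41 ± 0.169, and COL1A1 was well above background on 2 of 6 late arrays. Of 16 epithelial genes, 8 rose, 4 fell and 4 did not pass (camera adjusted p = 0.386), with a median of 0.37 that became -0.03 with spike-in scaling. The transcription factor ELF3 and the junction protein TJP1 rose by 2.31 ± 0.146 and 1.87 ± 0.105, and the keratins KRT8 and KRT19 fell by 2.02 ± 0.173 and 1.78 ± 0.0991. Of 22 listed markers of leukocytes, endothelium and red cells 8 entered the test, for which being well above background at 1 time is enough. Of these 8, 3 rose and 5 did not pass (median 0.43, or 0.03 with spike-in scaling, camera adjusted p = 0.131). VWF, a clotting factor of endothelium, was at least 1.98-fold higher and the macrophage receptor CSF1R, well above background on 1 of 4 arrays of 0 h, rose by 1.92 ± 0.249. Of 20 listed acinar and endocrine markers of the pancreas 3 entered the test. Of these 3, 2 rose and 1 did not pass (median 0.46, or 0.05 with spike-in scaling, camera adjusted p = 0.386), with the islet hormone PPY up by 1.31 ± 0.207, from 2 of 4 arrays of 0 h well above background.

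Further list members picked by the rule passed, but lost their calls under at least 1 alternative. The chemokine CCL20 rose by 2.36 ± 0.618, OASL, well above background on 1 of 4 arrays of 0 h, by 1.44 ± 0.477, the glycine transporter SLC6A9 by 1.00 ± 0.202, the lipid droplet protein PLIN2 by 1.00 ± 0.074, the receptor kinase AXL by 0.90 ± 0.216, TYROBP by 0.74 ± 0.248 and CHGA by 0.46 ± 0.17, and STARD4 was at least 1.50-fold higher. The carnitine enzyme CPT2 fell by 1.36 ± 0.441 and the aldolase ALDOC by 1.35 ± 0.368. Over the alternatives adjusted p reached 0.0814, 0.209, 0.187, 0.0572, 0.101, 0.111, 0.758, 0.165, 0.132 and 0.0583 in that order, from 1.17e-08, 1.38e-07, 0.000125, 7.52e-07, 0.00214, 0.0133, 0.00406, 6.74e-05, 4.52e-08 and 0.00054. With the slide as a block, STARD4 and CHGA lost their calls (limma adjusted p = 0.0598 and 0.0693). In addition ACSL3 with a rise of 0.95 ± 0.129 and ATP5F1C with a fall of 0.51 ± 0.0859, lost their calls, as NDUFB5 did, only under a minimum change of 2-fold. Another probe of ACSL3, well above background on all 10 arrays, gave -0.02. Other probes as well measured gave -0.09 and -1.15 for LDHA, 0.75 for MYC, 1.10 for SREBF2, 0.85 for TJP1, 1.10 to 1.56 for VEGFA and -1.65 to -1.21 for HSP90AA1. For DNAJA1 they gave -3.40 and -1.65.

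The time points were then compared one by one with 0 h. Every gene named for a time point had both of its arrays beyond all 4 arrays of 0 h. The slide block moved list medians by at most 0.176 at any time point, and turned the sign of the cholesterol median at 6 h and of the mesenchymal median at 3 h and 48 h, each within 0.1 of 0.

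At 3 h, 17 of 20 genes of inflammation and 17 of 29 of the integrated stress response had already risen, and 8 of 19 heat shock genes had fallen. SELE was at least 9.32-fold higher, the granulocyte growth factor CSF3 at least 8.81-fold and the interferon IFNL1 at least 7.99-fold, with limma adjusted p of 2.43e-06, 2.05e-06 and 5.94e-05. TXNIP fell by 2.29 ± 0.0925 (adjusted p = 1.18e-07). HSPA6, an inducible HSP70, was at least 6.56-fold lower and the arrestin ARRDC4, a relative of TXNIP, was lower by 2.42 ± 0.331 log2 units and well above background on 1 of 2 arrays, and both calls were lost with normexp (adjusted p = 0.13 and 0.0724, the highest among the alternatives tried, from 3.74e-06 and 1.47e-05). Of 20 NF-kB and inflammatory genes, 17 rose and 1 fell, with a median of 1.05, or 0.87 with bounds, and within-slide medians of 0.962 to 1.02 (camera adjusted p = 7.57e-15, adjusted p = 0.0257 with an estimated correlation). The feedback inhibitor TNFAIP3 rose by 2.83 ± 0.0997. Of 29 ATF4 targets, 17 rose and 1 fell, or 22 and 1 adjusted over the list alone, with a median of 0.78 and within-slide medians of 0.86 to 0.966 (camera adjusted p = 8.56e-16, adjusted p = 0.0349 with an estimated correlation). DDIT3 rose by 3.23 ± 0.077 and ATF3 by 2.98 ± 0.0815. Of 16 FOXO targets, 12 rose and 1 fell, or 14 and 1 adjusted over the list alone, with a median of 1.15 and within-slide medians of 1.05 to 1.16 (camera adjusted p = 1.96e-10, adjusted p = 0.0133 with an estimated correlation). Of 19 cell cycle inhibitors and p53 targets, 11 rose and none fell, or 12 and 2 adjusted over the list alone (median 0.29, camera adjusted p = 2.02e-05, adjusted p = 0.0468 with an estimated correlation). Of 19 heat shock genes, 8 fell and none rose, or 9 and none adjusted over the list alone (median -0.31, camera adjusted p = 0.000292, adjusted p = 0.0802 with an estimated correlation). Of 12 amino acid transporters 5 rose and 1 fell, or 6 and 1 adjusted over the list alone, and of 22 autophagy genes 7 rose and none fell, or 9 and 2. Both lists passed with medians of 0.27 and 0.24 (camera adjusted p = 0.0158 for each, adjusted p = 0.074 for each with an estimated correlation), and both calls were lost without replicate 2 of 3 h, with medians of 0.33 and 0.28 (adjusted p = 0.17 and 0.31, the highest among the alternatives, from 0.00258 and 0.00633). The transporter call was also lost with normexp (median 0.32, adjusted p = 0.0898). No glycolysis gene of 19 passed.

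At 3 h 2444 of 12695 genes passed, 1294 higher and 1150 lower. With the slide as a block 1532 passed, with normexp 312, and scaled to the spike-in probes 963 higher and 549 lower. The replicate arrays of 3 h differed by an SD of 0.428 over 11112 genes and those of 6 h by 0.369, against 0.15 to 0.264 at other times.

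At 6 h the same classes of genes were higher, immediate early genes now passed as well, and ribosome biogenesis genes were lower. SELE was at least 43.2-fold higher and CSF3 at least 23.9-fold, and NEURL3 rose by 6.02 ± 0.117, with limma adjusted p of 3.86e-08, 6.54e-08 and 4.41e-10. The sphingosine phosphate receptor S1PR5 fell by 3.62 ± 0.184 (adjusted p = 1.68e-07) and was well above background on 1 of 2 arrays. PAQR9 and HSPA2 were at least 5.25-fold and 4.17-fold lower, but with normexp PAQR9 lost its call (adjusted p = 0.811, from a range of 1.2e-07 to 0.811) and HSPA2 turned to +0.28. Of 29 ATF4 targets 24 rose and none fell, with a median of 1.43 and within-slide medians of 1.31 to 1.43 (camera adjusted p = 2.83e-12, adjusted p = 0.0346 with an estimated correlation). Of 20 inflammatory genes 18 rose and 1 fell, with a median of 1.31 and within-slide medians of 1.16 to 1.38 (camera adjusted p = 1.09e-10, adjusted p = 0.0339 with an estimated correlation). Of 20 immediate early genes 16 rose and 3 fell, with a median of 1.28 (camera adjusted p = 2.41e-07, adjusted p = 0.0339 with an estimated correlation), and the growth factor response gene EGR1 rose by 3.54 ± 0.129. Of 16 FOXO targets 12 rose and 1 fell, or 13 and 1 adjusted over the list alone, with a median of 1.44 (camera adjusted p = 4.91e-08, adjusted p = 0.0319 with an estimated correlation). Of 30 ribosome biogenesis genes 14 fell and 1 rose, or 15 and 1 adjusted over the list alone, with a median of -0.31, or -0.61 with normexp (camera adjusted p = 0.00194, adjusted p = 0.0346 with an estimated correlation). RRS1 fell by 2.20 ± 0.104.

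Other lists also passed at 6 h. Of 22 autophagy genes 14 rose and 2 fell (median 0.55, or 0.47 with bounds and 0.34 with normexp, camera adjusted p = 0.000726, adjusted p = 0.0339 with an estimated correlation), a call lost with normexp (adjusted p = 0.135, from a range of 0.000245 to 0.135). Of 18 interferon-stimulated genes 10 rose and 2 fell (median 0.60, camera adjusted p = 0.0019, adjusted p = 0.0978 with an estimated correlation). Of 19 heat shock genes 13 fell and none rose (median -0.51, camera adjusted p = 0.0019, adjusted p = 0.111 with an estimated correlation). Of 32 replication genes 14 fell and none rose (median -0.27, camera adjusted p = 0.00475, adjusted p = 0.245 with an estimated correlation), a call lost without replicate 2 of 6 h (adjusted p = 0.0547, from a range of 4.05e-07 to 0.0547). Of 19 cell cycle inhibitors and p53 targets 12 rose and 3 fell, or 14 and 3 adjusted over the list alone (median 0.43, camera adjusted p = 0.000377, adjusted p = 0.0519 with an estimated correlation). Of 31 lysosomal genes 13 rose and 2 fell, of 12 amino acid transporters 8 and 2, and of 23 apoptosis regulators 9 and 2, or 12 and 2 adjusted over the list alone. These lists passed with medians of 0.27, 0.51 and 0.22 (camera adjusted p = 0.000877, 0.00578 and 0.00224, adjusted p = 0.149, 0.0519 and 0.194 with an estimated correlation). All 3 calls were lost with normexp, with medians of 0.13, 0.48 and 0.15 and adjusted p of 0.525, 0.118 and 0.154, the highest among the alternatives, from 0.000361, 0.00125 and 0.00125. In all 5865 genes passed, 2545 higher and 3320 lower. The slide block left 5138, and with normexp 2906 were higher and 1641 lower.

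At 12 h the median of replication genes lay further below 0 h than at 6 h, and chaperones of the endoplasmic reticulum now passed. SELE was at least 41.4-fold higher and TNFAIP6, a hyaluronan-binding protein, at least 14.4-fold, and NEURL3 rose by 5.90 ± 0.117, with limma adjusted p of 1.68e-08, 3.04e-08 and 4.06e-10. S1PR5 was at least 11.6-fold lower, FAM111B at least 5.30-fold and PAQR9 at least 4.29-fold, with adjusted p of 5.16e-09, 3.31e-07 and 3.04e-07. Of 32 replication genes 29 fell and none rose, with a median of -1.19 and within-slide medians of -1.29 to -1.22 (camera adjusted p = 2.7e-08, adjusted p = 0.0755 with an estimated correlation). Of 23 chaperone genes 15 rose and 3 fell, or 16 and 3 adjusted over the list alone, with a median of 0.51 and within-slide medians of 0.458 to 0.51 (camera adjusted p = 0.00282, adjusted p = 0.115 with an estimated correlation). HSPA5 had risen by 2.71 ± 0.18. Of 29 ATF4 targets 22 rose and 2 fell (median 1.48, camera adjusted p = 1.1e-07, adjusted p = 0.104 with an estimated correlation). Of 16 FOXO targets 13 rose and 1 fell, or 15 and 1 adjusted over the list alone (median 1.55, camera adjusted p = 8.95e-06, adjusted p = 0.0755 with an estimated correlation). Of 20 inflammatory genes 16 rose and 2 fell, and of 20 immediate early genes 14 rose and 1 fell, with medians of 1.00 and 1.01 (camera adjusted p = 4.71e-05 for each, adjusted p = 0.113 and 0.0755 with an estimated correlation). Of 31 lysosomal genes 18 rose and 2 fell (median 0.48, camera adjusted p = 0.000543, adjusted p = 0.115 with an estimated correlation). Of 19 heat shock genes 14 fell and 1 rose (median -0.94, camera adjusted p = 0.00105, adjusted p = 0.109 with an estimated correlation). Of 18 interferon-stimulated genes 11 rose and 3 fell, and of 12 amino acid transporters 9 rose and 2 fell, each with a median of 0.91 (camera adjusted p = 0.00374 and 0.0063, adjusted p = 0.114 and 0.0755 with an estimated correlation). Of 22 autophagy genes 14 rose and 4 fell, of 23 apoptosis regulators 13 and 2, of 19 cell cycle inhibitors 11 and 4, or 12 and 4 adjusted over the list alone, and of 30 ribosome biogenesis genes 1 and 14. These lists passed with medians of 0.58, 0.40, 0.45 and -0.30 (camera adjusted p = 0.0056, 0.00587, 0.00698 and 0.0209, adjusted p = 0.0755, 0.214, 0.115 and 0.104 with an estimated correlation). Mitotic genes fell in 16 of 30 cases and rose in 7, or 17 and 7 adjusted over the list alone, and the list did not pass (median -0.28, camera adjusted p = 0.0588), but it did with the slide as a block (median -0.31, adjusted p = 0.0461). In all 7621 genes passed, 3514 higher and 4107 lower, against 7225 with the slide as a block and 4077 with normexp.

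**Figure D2:**
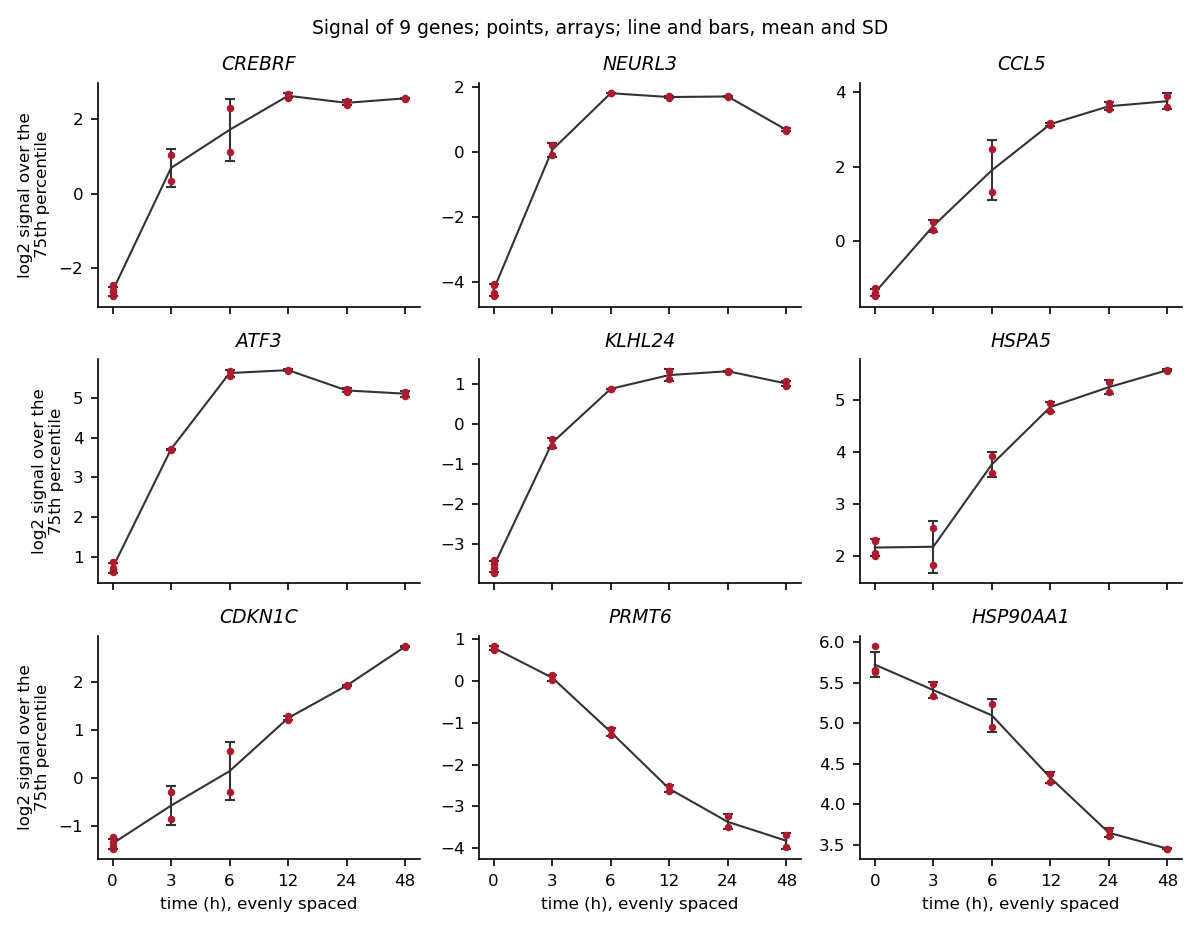
Normalized log2 signal of 9 genes on each array (y axis, log2 units relative to the array's 75th percentile) against hours in nutrient-deprived medium (x axis), with group means joined and bars of 1 SD. ATF3 is higher by 2.98 at 3 h and by 4.37 at 48 h, whereas HSPA5 is higher by 0.01 at 3 h and by 3.43 at 48 h.

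At 24 h mitotic genes passed as lower with and without the slide block. SPINK1 was at least 22.6-fold higher and SELE at least 17.5-fold, and NEURL3 rose by 5.92 ± 0.117, with limma adjusted p of 4.53e-07, 3.42e-08 and 2.85e-10. HAS3 was at least 15.2-fold lower, the checkpoint protein CLSPN at least 9.53-fold and RIBC2 at least 6.77-fold, with adjusted p of 5.15e-07, 1.71e-06 and 5.91e-09. Of 30 mitotic genes 24 fell and 1 rose, or 25 and 1 adjusted over the list alone, with a median of -0.95 and within-slide medians of -0.963 to -0.911 (camera adjusted p = 9.45e-07, adjusted p = 0.196 with an estimated correlation). Of 32 replication genes 31 fell and none rose, with a median of -1.89 (camera adjusted p = 1.01e-11, adjusted p = 0.0877 with an estimated correlation). Of 23 chaperone genes 20 rose and 1 fell, and of 31 lysosomal genes 25 rose and 1 fell, or 25 and 2 adjusted over the list alone. Their medians were 0.96 and 0.84, or 0.64 and 0.53 with spike-in scaling (camera adjusted p = 9.73e-06 and 1.56e-05, adjusted p = 0.0892 and 0.105 with an estimated correlation). Of 16 FOXO targets 12 rose and 2 fell, and of 29 ATF4 targets 19 rose and 5 fell, with medians of 1.45 and 1.13 (camera adjusted p = 0.00177 and 0.00178, adjusted p = 0.0892 and 0.323 with an estimated correlation). Of 19 heat shock genes 14 fell and 1 rose, or 14 and 2 adjusted over the list alone (median -1.08, camera adjusted p = 0.00178, adjusted p = 0.145 with an estimated correlation). Of 22 autophagy genes 14 rose and 4 fell, or 14 and 5 adjusted over the list alone, of 19 cell cycle inhibitors 11 and 4, of 23 apoptosis regulators 14 and 4, and of 30 ribosome biogenesis genes 3 and 16. These lists passed with medians of 0.97, 0.62, 0.54 and -0.46, or 0.65, 0.30, 0.22 and -0.78 with spike-in scaling (camera adjusted p = 0.0049, 0.0297, 0.0412 and 0.0121, adjusted p = 0.0892, 0.231, 0.352 and 0.0892 with an estimated correlation). Without the filter the cell cycle inhibitor and apoptosis calls were lost (adjusted p = 0.0516 and 0.0649, the highest among the alternatives, from 0.0169 and 0.0143). Inflammatory genes, 11 of 20 up and 6 down, or 11 and 7 adjusted over the list alone, did not pass as a list (median 0.45, or 0.14 with spike-in scaling, camera adjusted p = 0.204). In all 8536 genes passed, 4302 higher and 4234 lower. Against that, 7858 passed with the slide as a block and 4999 with normexp. Scaled to the spike-in probes, whose signal against the 75th percentile was 0.315 higher than at 0 h, 2433 were higher and 5645 lower.

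At 48 h the falls in cell cycle genes and, except with spike-in scaling, the rises in chaperone and lysosomal genes were larger in median than at 24 h, and the median of the inflammatory list lay below its level at 0 h. SPINK1 was at least 39.2-fold higher, the cyclin CCND2 at least 14.6-fold and MMP10 at least 13.8-fold, with limma adjusted p of 1.35e-07, 5.17e-07 and 1.18e-08. CDC25A was at least 35.4-fold lower, MKI67 at least 13.7-fold and the transcription factor E2F8 at least 13.6-fold, with adjusted p of 2.58e-09, 2.64e-09 and 3.99e-11. Of 32 replication genes 31 fell and none rose, with a median of -2.65, or -2.64 with bounds (camera adjusted p = 5.11e-12, adjusted p = 0.0816 with an estimated correlation). Of 30 mitotic genes 29 fell and 1 rose, with within-slide medians of -2.03 to -1.87 (camera adjusted p = 1.36e-10, adjusted p = 0.106 with an estimated correlation). Of 23 chaperone genes 22 rose and none fell, with a median of 1.44, or 0.53 with spike-in scaling (0.64 at 24 h), and within-slide medians of 1.44 to 1.60 (camera adjusted p = 3.67e-07, adjusted p = 0.0832 with an estimated correlation). Of 31 lysosomal genes 27 rose and 3 fell, with a median of 1.31, or 0.40 with spike-in scaling (0.53 at 24 h, camera adjusted p = 7.88e-06, adjusted p = 0.106 with an estimated correlation). Of 19 heat shock genes 13 fell and 3 rose (median -1.001, or -1.91 with spike-in scaling, camera adjusted p = 0.0105, adjusted p = 0.187 with an estimated correlation), and HSPA6 rose by 1.66 ± 0.186. Of 22 autophagy genes 15 rose and 5 fell, and of 30 ribosome biogenesis genes 16 fell and 4 rose, with means of 0.85 and -0.51 (camera adjusted p = 0.0214 and 0.0307, adjusted p = 0.106 for each with an estimated correlation). With spike-in scaling 10 autophagy genes rose and 9 fell, and the medians of 1.02 and -0.46 became 0.12 and -1.37.

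Of 16 FOXO targets at 48 h, 12 rose and 4 fell, with a median of 1.08, or 0.92 with bounds (camera adjusted p = 0.0337, adjusted p = 0.187 with an estimated correlation), but with spike-in scaling 7 rose and 5 fell, with a median of 0.17. Without the 3 h and 6 h arrays of slide 1 the list call was lost (adjusted p = 0.0554, from a range of 0.000604 to 0.0554). Of 29 ATF4 targets 17 rose and 7 fell, with a median of 0.82 that became -0.09 with spike-in scaling and 0.41 under quantile normalization (camera adjusted p = 0.0409, adjusted p = 0.571 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.064, from a range of 0.000631 to 0.064). With spike-in scaling 12 of these targets rose and 13 fell. Inflammatory genes rose in 7 of 20 cases and fell in 10 (median -0.22, or -1.13 with spike-in scaling and -0.45 under quantile normalization, camera adjusted p = 0.558). Of 18 interferon-stimulated genes the median was -0.08, or -0.99 with spike-in scaling, and the mean 0.09. Of the 8 tested among 22 listed markers of leukocytes, endothelium and red cells, 7 rose and none fell (median 0.96, camera adjusted p = 0.0635), but with spike-in scaling 2 rose and 2 fell (median 0.06). A marker bright only at 48 h could enter this test, which favours rises. In all 9441 genes passed, 5032 higher and 4409 lower. Against that, 8994 passed with the slide as a block and 6261 with normexp. Scaled to the spike-in probes, whose signal against the 75th percentile was 0.908 higher than at 0 h, 1303 were higher and 8465 lower.

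**Figure D3:**
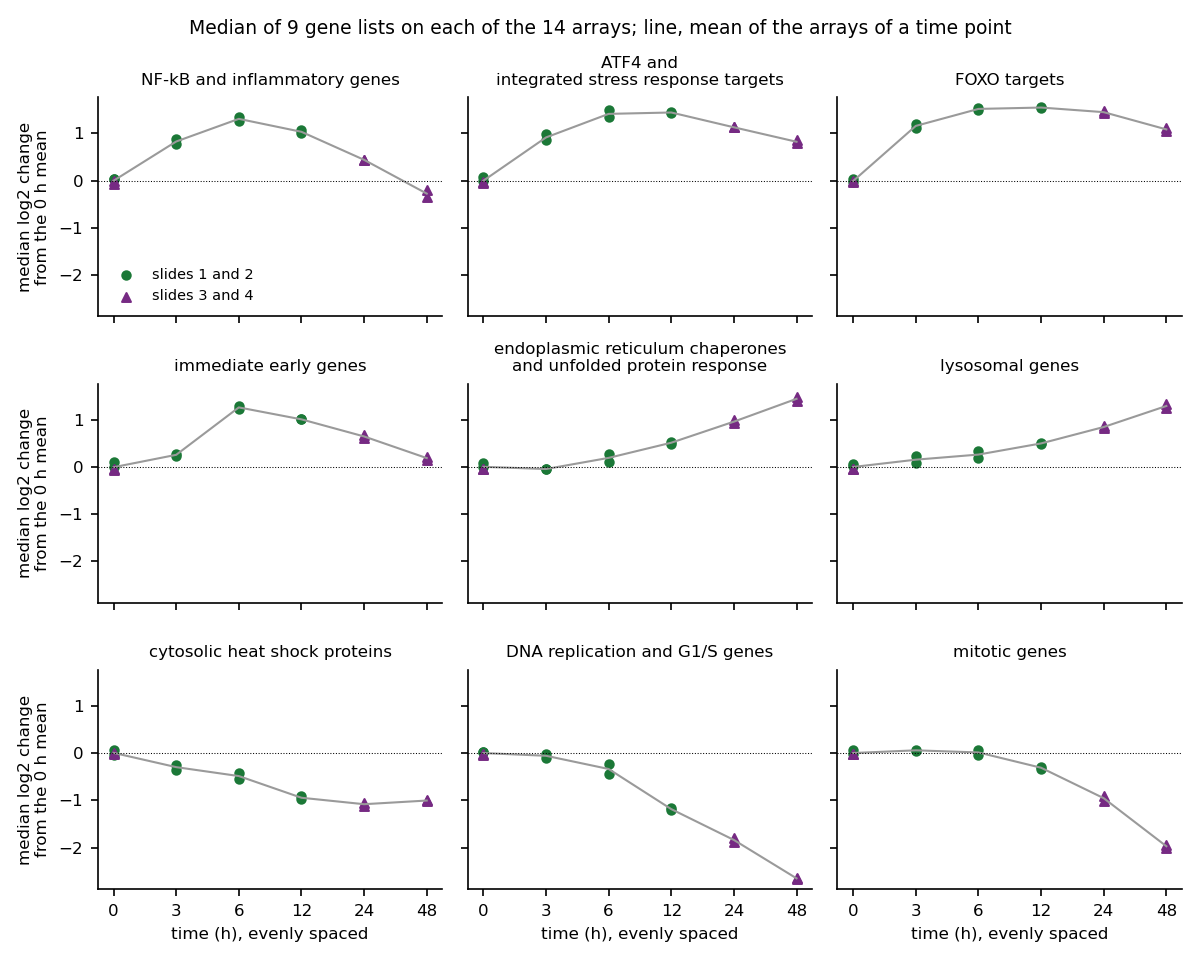
Median log2 change against 0 h of 9 gene lists (y axis, log2 units) at each time point (x axis, hours), with the median on each array, relative to the 0 h mean, as a point and the mean of the arrays as a line. In the fit the inflammatory list is at 1.31 at 6 h and -0.22 at 48 h, and the replication list at -0.03 at 3 h and -2.65 at 48 h.

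Neighbouring time points were compared to show when genes moved. Between 3 and 6 h immediate early genes rose: 14 of 20 rose and none fell, or 16 and none adjusted over the list alone, with a median of 0.79 and within-slide medians of 0.658 to 0.776 (camera adjusted p = 3.84e-11, adjusted p = 0.0301 with an estimated correlation). Of 18 interferon-stimulated genes 8 rose and none fell, or 9 and none adjusted over the list alone (median 0.49, or 0.32 with normexp, camera adjusted p = 2.8e-05, adjusted p = 0.0545 with an estimated correlation). Of 29 ATF4 targets 14 rose and none fell, or 15 and none adjusted over the list alone (median 0.33, camera adjusted p = 9.17e-06, adjusted p = 0.207 with an estimated correlation). The zinc finger gene ZNF554 rose by 3.23 ± 0.139 (limma adjusted p = 2.16e-06), and CIDEA, a lipid droplet protein, was at least 3.38-fold higher. Genes that passed numbered 3199, with 1403 higher and 1796 lower, against 2916 with the slide as a block, 1540 with normexp and 2070 scaled to the spike-in probes.

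Between 6 and 12 h replication genes fell: 23 of 32 fell and none rose, or 27 and none adjusted over the list alone, with a median of -0.83 and within-slide medians of -0.837 to -0.759 (camera adjusted p = 3.04e-14, adjusted p = 0.0494 with an estimated correlation). Inflammatory genes fell in 12 of 20 cases and rose in 1 (median -0.46, or -0.24 with normexp, camera adjusted p = 0.00109, adjusted p = 0.421 with an estimated correlation). Of 30 mitotic genes 12 fell and none rose, or 13 and none adjusted over the list alone (median -0.30, or -0.13 with normexp, camera adjusted p = 0.000229, adjusted p = 0.421 with an estimated correlation). Of 23 chaperone genes 11 rose and 1 fell, or 13 and 1 adjusted over the list alone (median 0.36, camera adjusted p = 0.000755, adjusted p = 0.4 with an estimated correlation). Genes that passed numbered 3327, with 1480 higher and 1847 lower, against 3161 with the slide as a block, 1004 with normexp, 2153 without replicate 1 of 6 h, and 1916 or 1772 without replicate 1 or 2 of 12 h. Scaled to the spike-in probes, 721 were higher and 1462 lower.

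Between 12 and 24 h chaperone genes rose: 6 of 23 rose and none fell, or 12 and none adjusted over the list alone, with a median of 0.57 (camera adjusted p = 3.4e-07, adjusted p = 0.047 with an estimated correlation), but with spike-in scaling none rose and the median was 0.26. Of 30 mitotic genes 13 fell and none rose, or 20 and none adjusted over the list alone (median -0.65, camera adjusted p = 5.24e-13, adjusted p = 0.113 with an estimated correlation). Of 20 inflammatory genes 7 fell and none rose, or 8 and 1 adjusted over the list alone (median -0.48, or -0.79 with spike-in scaling, camera adjusted p = 6.59e-06, adjusted p = 0.182 with an estimated correlation). No slide held both times, so this comparison runs through the 0 h arrays of each slide, and no within-slide value exists. Genes that passed numbered 995, with 542 higher and 453 lower, against 3118 without the slide term, 208 without the filter, and 1 with normexp. Without replicate 1 or 2 of 12 h 189 or 265 passed, and without replicate 1 or 2 of 24 h 151 or 64. Scaled to the spike-in probes, 29 were higher and 757 lower. All 5 genes that the naming rule picked here lost their calls with normexp, at an adjusted p of 1 each.

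Between 24 and 48 h mitotic and inflammatory genes fell and chaperone genes rose. Of 30 mitotic genes 24 fell and none rose, with a median of -0.81, or -1.40 with spike-in scaling, and within-slide medians of -0.864 to -0.743 (camera adjusted p = 1.73e-11, adjusted p = 0.174 with an estimated correlation). Of 20 inflammatory genes 14 fell and 1 rose, with a median of -0.77, or -1.37 with spike-in scaling, and within-slide medians of -0.838 to -0.679 (camera adjusted p = 8.97e-06, adjusted p = 0.174 with an estimated correlation). Of 23 chaperone genes 16 rose and none fell, with a median of 0.57 that became -0.02 with spike-in scaling and 0.30 under quantile normalization (camera adjusted p = 3.73e-05, adjusted p = 0.174 with an estimated correlation). HSPA6 was at least 12.6-fold higher (limma adjusted p = 4.81e-06) and the muscle ubiquitin ligase TRIM63 at least 6.18-fold lower. Genes that passed numbered 4865, with 2509 higher and 2356 lower, against 4826 with the slide as a block, 270 with normexp, 3204 without replicate 1 of 24 h and 3159 without replicate 1 of 48 h. Scaled to the spike-in probes, 180 were higher and 7338 lower.

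**Figure D4:**
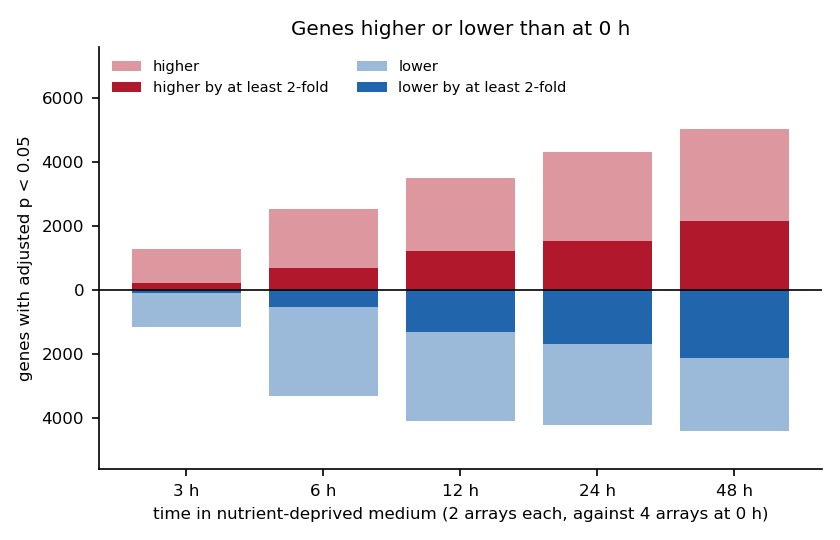
Number of genes past the test against 0 h at each time point (y axis, genes higher above and genes lower below 0, darker for changes of at least 2-fold) against hours (x axis). The total is 2444 at 3 h and 9441 at 48 h.

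As a check on the slides, the 0 h arrays of slides 1 and 2 were compared with those of slides 3 and 4. There 12 of 12695 genes passed, 3 higher and 9 lower, against 603 at an unadjusted threshold, and without replicates 1, 2, 3 or 4 in turn 26, 174, 27 and 29 passed. Changes were also set against each other across slide pairs that share no array. The 12 h change on slides 1 and 2 and the 24 h change on slides 3 and 4 had a Pearson r of 0.88 and a Spearman rho of 0.87 across 12587 genes, and 98.0% of the 2644 genes changed at least 2-fold at 12 h moved the same way. Against 48 h r was 0.712, and 92.8% moved the same way. These correlations are across genes, which are not independent replicates.

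**Figure D5:**
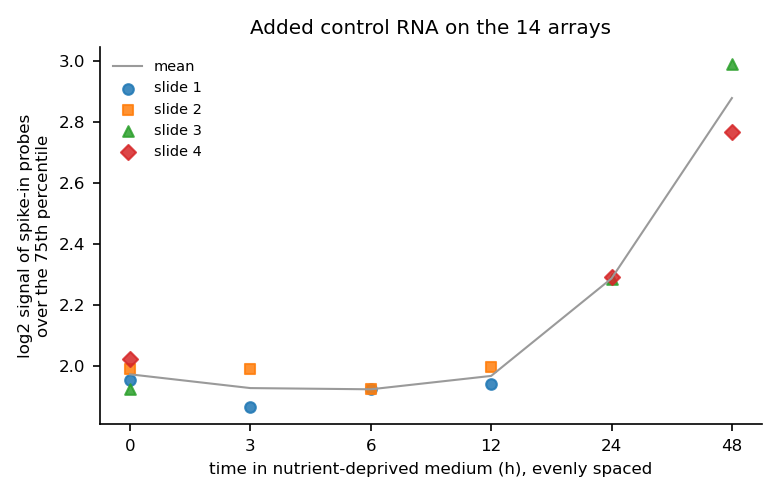
Signal of 5 spike-in probes relative to the 75th percentile of each array (y axis, log2 units), 1 point per array, against hours (x axis). The mean is 0.315 above the 0 h mean at 24 h and 0.908 above it at 48 h.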

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

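The splits of the arrays and the test of spot-level noise were chosen before their results were seen, and the tests on spike-in probes and on ribosomal protein genes were chosen after.

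Of the 210 possible splits of the 10 late and 0 h arrays into 6 and 4, 100 were drawn, and 1 of them, the real one, gave as many genes as the 7965 that limma called. Every other split puts 0 h and late arrays in one group, which widens the spread within it. Low counts were therefore likely there from the start, and no conclusion on chance is drawn. The highest of the other splits gave 0 genes by limma, and at an unadjusted threshold the highest other split gave 5789, against 8460 for the real one.

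Spike-in probes, which report a mix added to each sample, rose against the 75th percentile of the array by 0.315 at 24 h and by 0.908 at 48 h. Position on the slide is argued against by the 12 h arrays, which share the position of the 48 h arrays and differed from the 0 h arrays of their own slides by -0.0038. Slide or scan is argued against because the lower of the 2 within-slide differences at 48 h was still 0.746. The raw 75th percentile fell by 0.595 at 48 h (-0.595) while the raw spike-in signal rose by 0.313. A lower share of polyadenylated RNA in total RNA and a larger amount of added mix may each give these values and cannot be told apart here, because the amounts of RNA and mix per sample are not given in the sources used here.

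Replicates differed more at 3 h and 6 h than at other times, with SDs of 0.428 and 0.369. Spot-level noise on single arrays may explain part of this: at 3 h, the SD of the replicate difference for probes averaged over 5 or more spots was 0.491 times that of single-spot probes of like signal. The same ratio lay between 0.311 and 0.621 at other pairs, so averaging narrowed the differences there too. Averaged probes still differed by 0.218 at 3 h and 0.166 at 6 h, against 0.0755 to 0.101 elsewhere. Replicate 1 of each of these 2 times had the less even repeat spots, with coefficients of variation of 42.5% and 36.4% against 9.72% to 19.7% on other arrays, and what else differs between those arrays was not tested.

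At 48 h, genes of ribosomal proteins had a median change of 0.821, with 79 higher and 2 lower of 85 (camera adjusted p = 4.91e-09, adjusted p = 0.366 with an estimated correlation). High probe signal as the whole cause is argued against by other genes of like signal, whose median was 0.237, and 75 of 78 ribosomal protein genes lay above their matches. Spike-in scaling gave the family a median of -0.0867, but it lowers these genes, and nearly all others, by one amount, so it does not show whether scaling to the 75th percentile is the source, and that stays open. Quantile normalization gave 0.18. Whether these transcripts may be lost more slowly than others, or made in greater number, was not tested.

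Between 0 h arrays, 10 of 179 sets of 4 values had 1 array apart from the other 3 by Dixon's test, where about 1 in 20 is expected by chance. The mitotic median of replicate 1 was 0.0596 against -0.0223 to -0.00906 in the others. HSP90AA1 was 5.96 in replicate 1 against 5.63 to 5.66, and AXL 2.60 against 3.61 to 3.70. In replicate 2, ALDOC was -2.31 against -3.24 to -3.20, LIAT1 -1.93 against -3.54 to -3.28, NDUFB3 2.84 against 2.73 to 2.75 and ZNF614 -0.711 against -2.12 to -1.98. In replicate 3, GINS4 was -1.73 against -1.61 to -1.60 and MX1 -3.73 against -3.38 to -3.37, and in replicate 4 CCL20 was -2.57 against -2.76 to -2.74.

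Neighbouring times differed as follows, and the set tests among them come from 27 lists each. Between 3 and 6 h 3199 genes differed, with median changes of 0.326 for ATF4 targets, -0.307 for replication genes, 0.531 for FOXO targets, 0.24 for autophagy genes (0.09 with normexp), 0.162 for lysosomal genes (-0.127 with normexp), -0.368 for ribosome biogenesis, 0.492 for interferon-stimulated genes (0.32 with normexp), 0.794 for immediate early genes and 0.169 for apoptosis regulators (0.06 with normexp). In that order adjusted p with an estimated correlation was 0.207, 0.258, 0.0545, 0.0545, 0.258, 0.0545, 0.0545, 0.0301 and 0.258. Between 6 and 12 h 3327 genes differed, with 0.364 for chaperones, -0.299 for mitotic genes (-0.13 with normexp), -0.828 for replication genes, 0.236 for lysosomal genes (0.37 with normexp), -0.463 for inflammatory genes (-0.24 with normexp) and -0.279 for heat shock proteins, and adjusted p with an estimated correlation of 0.4, 0.421, 0.0494, 0.421, 0.421 and 0.421.

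Between 24 and 48 h 4865 genes differed, with 0.571 for chaperones (-0.02 with spike-in scaling, 0.30 under quantile normalization), -0.808 for mitotic genes, -0.4 for replication genes, 0.322 for lysosomal genes (-0.27 with spike-in scaling, 0.13 under quantile normalization), -0.774 for inflammatory, -0.401 for interferon-stimulated and -0.403 for immediate early genes, and adjusted p with an estimated correlation of 0.174, 0.174, 0.174, 0.395, 0.174, 0.228 and 0.395. Spike-in scaling moved the median of all genes to -0.548 there, and to -0.247 between 12 and 24 h, and lowered each list median with it. Between 12 and 24 h 995 genes differed, with -0.239 for ATF4 targets, 0.573 for chaperones (0.26 with spike-in scaling), -0.651 for mitotic genes, -0.684 for replication genes, 0.364 for lysosomal genes (0.05 with spike-in scaling), -0.476 for inflammatory genes, -0.505 for immediate early genes and -0.0971 for NRF2 targets (-0.17 under quantile normalization), and adjusted p with an estimated correlation of 0.16, 0.047, 0.113, 0.112, 0.148, 0.182, 0.143 and 0.148.

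Among single genes, changes between 3 and 6 h were at least 1.76 log2 units for CIDEA and 2.67 for HLF, 3.23 for ZNF554, and at least as low as -1.78 for SNX31, -2.33 for VWA3B and -1.20 for SLC1A3. From 6 to 12 h they were at least 1.33 for ANGPT2 and 1.84 for SMOC2, and at least as low as -2.38 for HLF, -1.37 for CIDEA and -0.372 for LIAT1. From 24 to 48 h they were at least 2.28 for FGF5, 3.65 for HSPA6 and 1.90 for GPLD1, and at least as low as -2.04 for ZAP70, -1.42 for ANGPT2 and -2.63 for TRIM63. From 12 to 24 h, with the slide in the model, they were 2.47 for GPNMB, 2.14 for ZFP41, 1.93 for ZNF614, -3.73 for RBM43 and at least as low as -0.856 for IL37. Some of these calls were lost with normexp: SNX31 and VWA3B between 3 and 6 h, with adjusted p up to 0.997 and 0.718 over the alternatives, from 0.000428 and 0.00591, HLF and LIAT1 between 6 and 12 h, up to 0.109 and 0.0897, from 0.000783 and 0.00329, and FGF5, GPLD1, ZAP70 and ANGPT2 between 24 and 48 h, up to 0.103, 0.194, 0.36 and 0.497, from 0.000524, 0.00187, 0.00703 and 1.15e-06. All 5 calls between 12 and 24 h were lost with it too, up to 1, each under at least 1 other setting as well, and SLC1A3, and ANGPT2 and SMOC2 between 6 and 12 h, changed sign. HLF between 3 and 6 h was lost without replicate 2 of 3 h or of 6 h and with the replicate block, up to 0.094, from 0.000812. VWA3B was also lost with the mean of all probes and without the 3 h and 6 h arrays of slide 1, HLF between 6 and 12 h with the replicate block and without replicate 1 or 2 of 12 h or replicate 2 of 6 h, and ZAP70 without the filter and without any 1 of its 4 arrays. In the main analysis limma adjusted p for these genes lay between 2.16e-06 and 0.0388, and in each case both arrays of one time lay beyond both of the other.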

How the results depend on the processing

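Spike-in scaling and leaving out the 48 h arrays or the 3 h and 6 h arrays of slide 1 were chosen after the data were seen, and the other settings before. The cause was not tested for any of the changes below.

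Normexp background correction changed the number of genes at 3 h to 312, at 12 h to 4077, at 24 h to 4999 and at 48 h to 6261, between 3 and 6 h to 1540, 6 and 12 h to 1004, 24 and 48 h to 270, 12 and 24 h to 1, and in the 0 h check, to 0 by limma (147 unadjusted). It turned 4 single-gene changes, HSPA2 at 6 h to 0.2823, SLC1A3 between 3 and 6 h to 0.1114, and ANGPT2 and SMOC2 between 6 and 12 h to -0.3349 and -0.2274. A minimum of 2-fold left 3015 genes in the late comparison, 303 at 3 h, 1218 at 6 h, 2528 at 12 h, 3229 at 24 h, 4287 at 48 h, 430 between 3 and 6 h, 394 between 6 and 12 h, 618 between 24 and 48 h and 241 between 12 and 24 h. The slide block left 1532 at 3 h, and without it 3118 passed between 12 and 24 h. The replicate block, although numbers did not pair the samples (3 of 15 correlations over 0.1), left 5190 late, 1158 at 3 h and 2411 between 12 and 24 h.

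Spike-in scaling gave 1512 genes at 3 h, 2070 between 3 and 6 h, 2183 between 6 and 12 h and 7518 between 24 and 48 h. Between 12 and 24 h 208 passed without the filter and 3046 without the 3 h and 6 h arrays of slide 1. The 0 h check gave 1 with the strict filter and 7 with an intensity trend. Without the 48 h arrays 8617 genes passed in the late comparison, 7519 of them shared with the 7965.

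With an estimated correlation 0 of 27 camera list tests passed late (6 unadjusted), against 11 at the preset one, and 10 of 135 at the time points, against 54.

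Leaving out 1 array at a time, where a lone sample is assumed to vary like the other groups, gave 6972 to 8254 genes late, 1598 to 4812 at 3 h, 4875 to 5646 at 6 h, 6327 to 7465 at 12 h, 7262 to 8358 at 24 h, 8405 to 9364 at 48 h, 2288 to 5135 between 3 and 6 h, 1772 to 3811 between 6 and 12 h, 3159 to 3341 between 24 and 48 h, 64 to 265 between 12 and 24 h and 26 to 174 in the 0 h check. Lists past were 9 to 13 late and 52 to 59 at the time points.

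Over all alternatives, list calls were the same 2235 times (signs could differ), lost 85 times and gained 56 times. Named genes were the same 3674 times, lost a call 87 times and turned 4 times. Slide and replicate blocks were not run for the 0 h check, where the model cannot be estimated.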

Other observations

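The tests of gene families below were chosen after the data were seen, with 40 families defined by symbol. Circadian clock genes were higher at late times: 7 of 9 rose and none fell, with a median of 1.16 (camera adjusted p = 0.00227, adjusted p = 0.22 with an estimated correlation), or 0.76 with spike-in scaling. NR1D1 (REV-ERB alpha), a repressor in the clock, rose by 2.79 ± 0.0839 (limma adjusted p = 7.84e-09), its relative NR1D2 by 2.77 ± 0.164, and the period gene PER1 by 2.97 ± 0.203. CRY1 and CRY2 rose by 1.16 ± 0.138 and 1.14 ± 0.131. BMAL1, which was not in the family, rose by 1.52 ± 0.142, and CLOCK did not pass (-0.10, adjusted p = 0.498). Subunits of the vacuolar proton pump rose in 13 of 18 cases and fell in 2, with a median of 0.72, or 0.31 with spike-in scaling (camera adjusted p = 0.00911, adjusted p = 0.577 with an estimated correlation). ATP6V1C1 and ATP6V1D rose by 1.21 ± 0.0764 and 1.10 ± 0.129. HLA genes rose in 10 of 11 cases, with a median of 0.95, or 0.54 with spike-in scaling (camera adjusted p = 0.00911, adjusted p = 0.577 with an estimated correlation). HLA-E rose by 1.19 ± 0.19, although near-identical copies can share probes.

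All 4 ID genes, inhibitors of differentiation, fell, with a median of -2.13, or -2.54 with spike-in scaling (camera adjusted p = 0.0162, adjusted p = 0.507 with an estimated correlation), ID1 by 3.59 ± 0.16, ID2 by 2.21 ± 0.14 and ID3 by 2.04 ± 0.30. Of 14 Kruppel-like factors 9 rose and 1 fell (median 0.73, or 0.33 with spike-in scaling, camera adjusted p = 0.00918, adjusted p = 0.331 with an estimated correlation), KLF11 and KLF9 by 1.99 ± 0.13 and 1.81 ± 0.16. Proteasome subunits fell in 26 of 34 cases and rose in 1 (median -0.61, or -1.02 with spike-in scaling, camera adjusted p = 6.84e-05, adjusted p = 0.466 with an estimated correlation), PSMB6 by 1.46 ± 0.12, and PSMB10 rose by 0.44 ± 0.088. Mitochondrial ribosomal proteins fell in 41 of 77 cases and rose in 4 (median -0.35, or -0.76 with spike-in scaling, camera adjusted p = 0.000659, adjusted p = 0.331 with an estimated correlation). Nucleoporins fell in 15 of 21 cases and rose in 2 (median -0.80, or -1.21 with spike-in scaling, camera adjusted p = 0.00534, adjusted p = 0.577 with an estimated correlation), NUP155 by 1.34 ± 0.0928. Tubulins fell in 9 of 15 cases (median -0.92, or -1.33 with spike-in scaling, camera adjusted p = 0.0154, adjusted p = 0.577 with an estimated correlation), with TUBB4B down by 2.22 ± 0.38 (-2.22) and TUBB2B up by 1.23 ± 0.12.

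Interferon, interleukin and chemokine genes, without their receptors, rose in 16 of 29 cases and fell in 1 (median 0.97, or 0.56 with spike-in scaling, camera adjusted p = 0.00455, adjusted p = 0.22 with an estimated correlation). Ribosomal proteins rose in 40 of 85 cases and fell in 2 (median 0.41, or 0.00 with spike-in scaling and 0.09 under quantile normalization, camera adjusted p = 0.000659, adjusted p = 0.736 with an estimated correlation). Keratins (median 0.03, or -0.38 with spike-in scaling, camera adjusted p = 0.391) and complex I subunits (median -0.18, or -0.58 with spike-in scaling, camera adjusted p = 0.0757) did not pass.

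Some single genes, picked after their values were seen, had their highest or lowest values at different times. CCL20, an inflammatory chemokine, was higher by 3.55 at 3 h, 4.26 at 6 h and 0.73 at 48 h, whereas CCL5 was higher by 1.80, 3.29 and 5.15 at the same times. NR4A1 was higher by 1.16 at 6 h and 4.80 at 48 h, while EGR1 was higher by 3.54 and 2.08. HSPA1A was lower by 2.52 (-2.52) at 3 h and 0.24 (-0.24) at 48 h, whereas HSP90AA1 was lower by 0.63 (-0.63) at 6 h and 2.27 (-2.27) at 48 h. These differences between genes in the time of change were not tested.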
